A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

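Total RNA from S. cerevisiae grown in the rich medium YPD was extracted with hot acid phenol, purified on RNeasy columns, amplified in 1 round from an oligo-dT primer with a T7 promoter, labelled with biotin and hybridised to one-colour Affymetrix arrays, per the labels' protocols. Oligo-dT priming makes the signal depend on RNA integrity toward the 5' end of a transcript. The series' design states that each strain was grown as independent cultures, so the p-values here cover the spread between cultures. The strains are of the FY background, per the labels. There were 4 arrays, 2 labelled hst3hst4 and 2 labelled wild-type, grouped by those labels.

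The deposited values are linear intensity signals per probe set. GCOS 1.4 and MAS5 are named in the submitters' processing notes; the version of MAS5 and the scale target are not given in the sources used here. The mean signal after trimming 2% at each end was 150.2 on every array, so the deposited signals had been scaled per array to a common mean. This scaling makes changes relative to the average gene. The table used here holds no detection calls, so no probe set was classed as present or absent; dim probe sets were handled by a filter. MAS5 subtracts mismatch signals, which makes low values noisy, and signals from 0 occur.

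Of 9335 probe sets, 60 control probe sets were left out and 9275 S. cerevisiae probe sets kept. Probe sets were named through the platform annotation, with symbols updated by gene identifier to the RefSeq table of the R64 assembly: 6504 had 1 gene, all of which matched that table, 328 had several and 2443 had none listed. No gene was named from a probe set with several. Where a gene had more than 1 probe set, the one with the highest mean log2 signal represented it, which left 5271 genes. Positions are those of R64.

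Signals were transformed as log2(signal + 3.3), where 3.3 is the 10th percentile of all signals. A fold change on this scale understates the change of dim genes. The 20% of probe sets with the lowest mean log2 value over all arrays were left out (1855 probe sets, below a signal of about 8.97), and 7420 were tested. No further normalization between arrays was applied. The strains were compared with lmFit and eBayes with a mean-variance trend in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The fit has 2 residual degrees of freedom and 5.75 prior degrees of freedom, and the median standard error of a log2 fold change was 0.219. Adjusted p-values of genes are from this limma fit. Data were simulated with the real means of 7420 probe sets and independent normal noise. The noise variance was the average of each probe set's own variance and that of the fitted trend. Unlike these data, the simulated ones had no shared variation between genes and the same spread in both strains. On them the fit recovered 48% of 100 probe sets changed 2-fold and 83% of 100 changed 4-fold, and called 4 unchanged ones. With no change it called 0. Smaller changes are therefore often missed.

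Before the data were examined, 33 gene lists were fixed, of which 32 had at least 3 measured genes and were tested with camera (preset correlation of 0.01) on 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists. The estimated correlation and fry were the alternatives. With an estimated correlation camera rests on the 2 residual degrees of freedom. The deleted sirtuin list (HST3 and HST4) had too few members and is given gene by gene. Of the listed symbols, 1 was not matched. In the cell wall list, the symbol MLP1 was matched to the current gene of that name, which acts at the nuclear pore, and prefix rules brought the RNase P gene RPP1 into the ribosomal protein list and COS111 into the subtelomeric list. Chromosomes, and the 8 outermost genes at each chromosome end, were tested with camera in the same way.

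The genes named in the text follow a rule fixed beforehand: HST3 and HST4; the 12 highest and 12 lowest called genes with the same sign in all 4 array pairs; for each list the 2 highest and 2 lowest members; all members of the lists for DNA damage, histones, markers and mating types; and the 3 members with the largest change for a result on chromosome ends. Other called members named in the text (DDR2, TFS1, YGP1, NTH1, CTS1, DSE2, YPS3, RPL5, SPS19, FLR1, SAM2, DAL1, URA1, GTT1 and YPS6) were chosen after their values were seen.

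The alternatives fixed beforehand were quantile normalization, centring on each array's median, a pseudocount of 1 or of the 25th percentile (12.9), no filter or a filter of 40%, no trend, 1 probe set per gene before the fit, the replicate number as a block, each array left out in turn, a 1.5-fold threshold, chromosome arms, and the 4 or 15 outermost genes. Scaling on 9 hybridisation control probe sets and leaving families out of the end genes were added after the data were seen. Figures were drawn with matplotlib from the same tables.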

Results

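Gene expression was measured in budding yeast, Saccharomyces cerevisiae, with 4 one-colour Affymetrix arrays: 2 labelled hst3hst4 and 2 labelled wild-type, each hybridised with RNA from its own culture in rich medium. HST3 and HST4 encode sirtuins, NAD-dependent deacetylases whose best known substrate is lysine 56 of histone H3. The design sets each mutant culture against each wild-type culture, which asks how transcript levels differ when both genes are deleted. The table held signals for 9275 yeast probe sets, of which 7420 were tested, and 5271 genes were represented by a probe set of their own. The median signal per array was 37.5 and 41.2 on the arrays labelled hst3hst4 and 37.9 and 38.3 on those labelled wild-type. Across probe sets the log2 signals of the 2 hst3hst4 arrays correlated with r = 0.984 and those of the 2 wild-type arrays with r = 0.971, against 0.953 to 0.966 between strains. These r values are across probe sets, which are not independent replicates. The number of arrays, 2 per strain, limits the precision of every value given here.

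Among RNA quality measures, the signal ratio of the 3' to the 5' control probe set of the TATA-binding protein gene was 3.82 and 3.70 on the hst3hst4 arrays and 4.64 and 5.20 on the wild-type arrays. The same ratio for ACT1, the actin gene, was 1.73 and 1.78 against 1.70 and 1.88. That for SRB4, a subunit of the RNA polymerase II mediator, was 2.34 and 1.90 against 1.87 and 1.63, opposite in direction to the TATA-binding protein gene. The bacterial and phage hybridisation controls, 9 probe sets, were lower on the hst3hst4 arrays by a mean log2 difference of -0.36, with all 9 in that direction. Scaling the arrays on these controls, a choice made after seeing the data, moved the median log2 fold change of all tested probe sets to 0.35, and the changes below are relative to the common trimmed mean to which the arrays were scaled.

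The deleted genes were read first, because they check the labels. HST3 (YOR025W, chromosome 15, 378219 to 379562 in the R64 assembly) had signals of 0.4 and 0.5 on the arrays labelled hst3hst4 and of 13.7 and 25.3 on those labelled wild-type. Its log2 fold change was -2.56 (SE 0.36), it fell below the filter on dim probe sets, and without that filter its adjusted p was 0.0654. HST4 (YDR191W, chromosome 4, 842337 to 843449) went against the labels. Its signal was 38.7 ± 0.919 (SD, n = 2) on the arrays labelled hst3hst4 and 2.25 ± 1.91 (SD, n = 2) on those labelled wild-type, a log2 fold change of 2.96 (SE 0.37, limma adjusted p = 0.0104). Where the HST4 probes lie relative to the deleted part was not given in the sources used here, and a probe set outside that part would check nothing. The groups are therefore named by their labels throughout, and every direction below is that of arrays labelled hst3hst4 against arrays labelled wild-type. The HST4 call, like most calls, was lost without hst3hst4 replicate 1 or without hst3hst4 replicate 2. Its log2 fold change was 2.98 without the former and 2.94 without the latter.

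In the comparison of the strains, HUG1, an inhibitor of ribonucleotide reductase induced by DNA damage, rose most. Its signal was 1904 ± 60.3 (SD, n = 2) on the arrays labelled hst3hst4 and 28.6 ± 6.65 (SD, n = 2) on the wild-type arrays, a fold of 60.4 on the log2(signal + 3.3) scale. PIR3, a cell wall glycoprotein, rose 12.1-fold, NCA3, of the SUN family of cell wall proteins, 11.9-fold, and RNR3, a large subunit of ribonucleotide reductase, 11.7-fold. The RNR3 log2 fold change of 3.55 was 2.66 without wild-type replicate 1 and 4.43 without wild-type replicate 2, and lost its call without either hst3hst4 array, with no filter and without a trend (highest adjusted p = 0.225). Among called genes with a probe set of their own the decreases were smaller, while a called probe set with no gene listed fell by 4.84. YOL014W, an uncharacterised open reading frame, fell by 1.35 on the log2 scale (SE 0.25), and EGT2, a cell wall endoglucanase that acts in cell separation, fell by 1.20 (SE 0.16).

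In all, 196 of 7420 probe sets passed an adjusted p of 0.05 in limma, 156 higher and 40 lower on the arrays labelled hst3hst4, and 1498 had an unadjusted p under 0.05. At the level of genes, 116 rose, 102 of them at least 2-fold, and 28 fell, 9 of them at least 2-fold. Each of these genes had the same sign in all 4 pairs of a mutant and a wild-type array. On the added scaling to the hybridisation controls, which shifts every probe set of an array alike, the split was 1166 higher and 23 lower. The count was 36 with no filter on dim probe sets, 38 without the mean-variance trend, 9 and 4 without hst3hst4 replicates 1 and 2, and 865 and 337 without wild-type replicates 1 and 2.

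The other genes among the 12 with the highest fold changes were HSP26, a small heat shock protein (log2 fold change 3.37, SE 0.26), BNA2, the tryptophan dioxygenase that starts de novo NAD synthesis (3.19, SE 0.48), the open reading frame YJR079W (2.99, SE 0.28), HST4, GND2, a 6-phosphogluconate dehydrogenase (2.76, SE 0.53), IRC18 (2.66, SE 0.35), HSP12, a small membrane-associated stress protein (2.65, SE 0.17), and SSA3, a stress-induced Hsp70 (2.63, SE 0.43). Leaving out a wild-type array moved GND2 to 1.83 or 3.70, BNA2 to 2.40 or 3.99 and SSA3 to 1.97 or 3.29. YJR079W overlaps BNA2 by 17 bp, so their signals may share a source, and a second probe set of YJR079W gave 0.57 (adjusted p = 0.474). After YOL014W and EGT2, the lowest log2 fold changes belonged to MMP1, an S-methylmethionine permease (-1.18, SE 0.21), SUN4, a cell wall protein of septation (-1.17, SE 0.15), ABF1, a DNA-binding general regulatory factor (-1.15, SE 0.23), and LEU2, the isopropylmalate dehydrogenase of leucine synthesis (-1.15, SE 0.12). MYO5, a type I myosin (-1.06, SE 0.20), STE6, the a-factor exporter (-1.05, SE 0.18), RAS2 (-1.01, SE 0.16), MET6, methionine synthase (-0.98, SE 0.16), LAT1, a subunit of pyruvate dehydrogenase (-0.97, SE 0.18), and DSE4, a daughter-cell glucanase (-0.96, SE 0.18), followed.

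A separate count took the design's pairwise comparison literally. At least a 2-fold difference in the same direction in all 4 array pairs was seen for 122 probe sets, 111 higher and 11 lower, and 106 of them also passed the limma test. They represent 84 genes that were higher and 4 that were lower, EGT2, LEU2, MMP1 and SUN4. The splits that put 1 mutant and 1 wild-type array on each side gave 4 and 4 such probe sets.

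The DNA damage list rose and held the gene with the highest fold change of all those tested, HUG1. Of 25 measured genes known to be induced by DNA damage, 5 rose, 1 fell and 19 did not pass the test; adjusted over the list alone, 7 rose and 1 fell. RNR2 and RNR4, the small subunits of ribonucleotide reductase, rose 2.83-fold and 2.76-fold from already high signals of 889 and 1047 on the wild-type arrays. DIN7, a mitochondrial nuclease, rose 2.98-fold, beside HUG1 and RNR3. DDR48, a stress protein also induced by heat, fell by 0.72 on the log2 scale (adjusted p = 0.0358), while its second probe set gave -0.38 (adjusted p = 0.234). RNR1, the main large subunit, had a log2 fold change of 0.81 (adjusted p = 0.165), PLM2 1.36 (0.0774) and DUN1, the checkpoint kinase, 0.92 (0.0748). The median of the list was 0.28 (camera adjusted p = 0.00038 with the preset correlation; adjusted p = 0.443 with an estimated correlation). Without wild-type replicate 2 the median was 0.48.

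**Figure D1:**
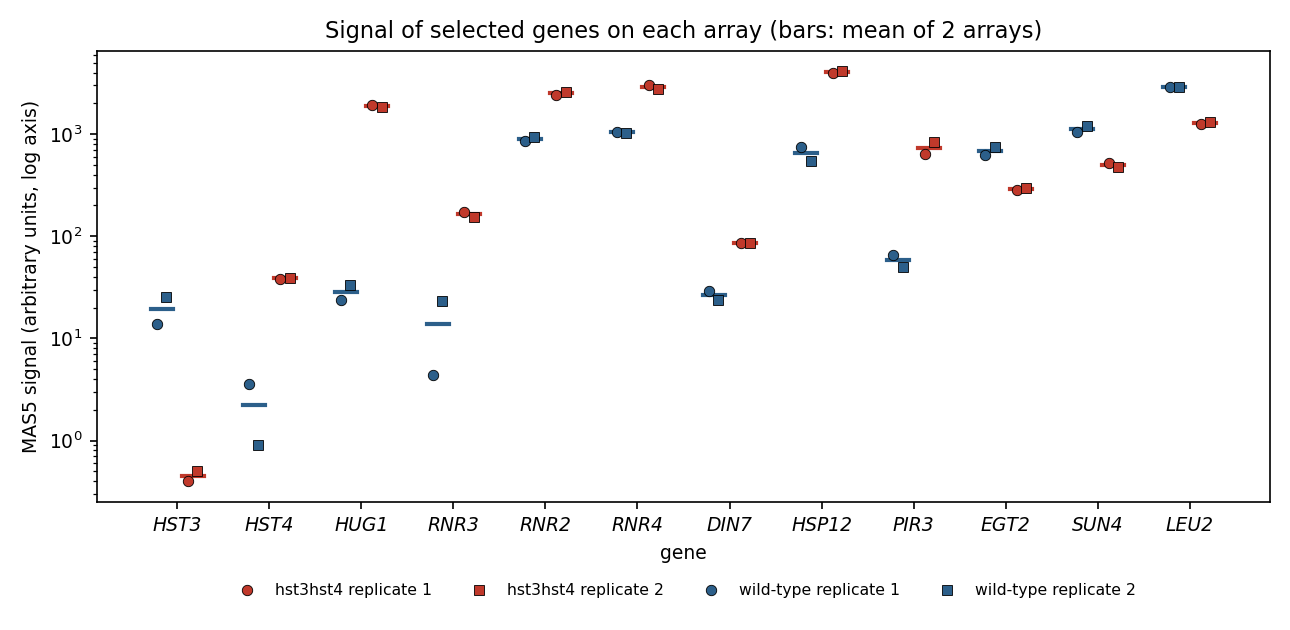
MAS5 signal in arbitrary units on a log axis for 12 genes on each of the 4 arrays, with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 arrays. HUG1 lay at 1946 and 1861 on the arrays labelled hst3hst4 against 23.9 and 33.3 on the wild-type arrays, while HST3 and HST4 differed in opposite directions.

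Lists for repair, replication and cell cycle control did not pass. None of 14 homologous recombination genes passed the limma test (list median 0.19, camera adjusted p = 0.109; 1 higher when adjusted over the list alone); TOP3, a topoisomerase, had the highest member value, 1.42 (adjusted p = 0.0593). Without wild-type replicate 2 this list passed (median 0.31, adjusted p = 0.0144), and without wild-type replicate 1 its median was 0.03 (adjusted p = 0.626). The 15 checkpoint genes had a median of -0.10 (camera adjusted p = 0.759), with TEL1 at 0.33 and MRC1 at -0.59, and 36 DNA replication genes had a median of -0.07 (camera adjusted p = 0.853), with CDC45 at 0.87 and RFC5 at -0.83. No member of either list passed, over all genes or adjusted over the list alone. The 16 genes of the other sirtuins and of the H3 lysine 56 acetylation pathway had a median of 0.01 (camera adjusted p = 0.995) and no call by either adjustment. Within it, HST2 had a log2 fold change of 0.48 (adjusted p = 0.172), SIR2 0.43 (0.314) and HST1 -0.46 (0.229). The 10 G1/S cyclins and regulators (median -0.02, camera adjusted p = 0.889; 1 lower adjusted over the list alone) included SVS1 at -0.68 (adjusted p = 0.0769), and the 13 G2/M genes (median -0.05, camera adjusted p = 0.622; 1 higher adjusted over the list alone) included SPO12 at 0.76 (adjusted p = 0.066).

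Genes expressed at the transition from M to G1 fell as a list, several of them encoding enzymes that separate mother and daughter cells. Of 15 measured, 5 fell, 1 rose and 9 did not pass; adjusted over the list alone, 11 fell and 1 rose. EGT2, DSE4, the glucanase DSE2 (log2 fold change -0.90), the chitinase CTS1 (-0.93) and PIR1 (-0.74) were the genes that fell. PIR3 was the exception, although PIR1 (YKL164C) and PIR3 (YKL163W), both cell wall glycoproteins, have successive locus names on chromosome 11. The list median was -0.74 (camera adjusted p = 2.0e-05; adjusted p = 0.483 with an estimated correlation). Among 17 cell wall and flocculation genes, PIR3, GSC2, a glucan synthase subunit (3.77-fold), and the aspartic protease YPS3 (log2 fold change 1.09) rose, PIR1 fell and 13 did not pass; adjusted over the list alone, 4 rose and 1 fell. Of the 5 other probe sets of GSC2, 2 passed (log2 fold changes 1.78 and 2.17) and 3 did not (1.10, 1.27 and 1.15, lowest adjusted p = 0.0793). On the cell wall list the wild-type cultures differed by a median of -0.090, and the median of the array pairs ran from 0.083 to 0.38. The median of that list was 0.21 (camera adjusted p = 0.030; adjusted p = 0.443 with an estimated correlation), and the call was lost without hst3hst4 replicate 1 or without wild-type replicate 1 (highest adjusted p = 0.152).

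The environmental stress genes rose as a list. Of 32 measured, 7 rose, 0 fell and 25 did not pass, and 12 rose when adjusted over the list alone. HSP26, HSP12 and SSA3 led it, with DDR2 (log2 fold change 2.46), the carboxypeptidase Y inhibitor TFS1 (1.75), the secreted glycoprotein YGP1 (1.65) and the trehalase NTH1 (1.12) behind them. The list median was 0.86 (camera adjusted p = 6.6e-09; adjusted p = 0.562 with an estimated correlation). The wild-type cultures differed from each other on this list by a median of 0.82, and the median of the 4 array pairs ran from -0.02 to 1.496. Without wild-type replicate 1 the list median was 1.402 and without wild-type replicate 2 it was 0.18. The 22 heat shock chaperones as a list did not pass (median -0.10, mean 0.19, camera adjusted p = 0.698). HSP26 and SSA3 rose, the constitutive Hsp70 SSA2 fell by 0.77 on the log2 scale and 19 members did not pass, with 4 higher and 4 lower when adjusted over the list alone.

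Of 39 respiration genes, 35 had a log2 fold change above 0, with a median of 0.37 (camera adjusted p = 7.9e-08; adjusted p = 0.519 with an estimated correlation). Of these only ATP5, a subunit of the ATP synthase, passed over all genes (2.07-fold), and 14 rose when adjusted over the list alone; QCR9 of complex III had a log2 fold change of 0.93 (adjusted p = 0.056). Without hst3hst4 replicate 2 the median was 0.24. Of 17 glucose-repressed genes, PCK1, the carboxykinase of gluconeogenesis, rose 2.85-fold and 16 did not pass; adjusted over the list alone, 3 rose and 1 fell. That list had a median of 0.28 (camera adjusted p = 0.0229; adjusted p = 0.443 with an estimated correlation), and its call was lost with the lowest 40% of probe sets left out and without wild-type replicate 2 (highest adjusted p = 0.144). For 15 glycolysis genes, of which 0 passed over all genes or adjusted over the list alone, the median was -0.21 (camera adjusted p = 0.00478; adjusted p = 0.443 with an estimated correlation), but 0.02 with an adjusted p of 0.988 after quantile normalization, and the call was also lost without hst3hst4 replicate 2.

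Ribosomal protein genes fell slightly as a list. Of 81 measured, 4 had a log2 fold change above 0, 3 fell over all genes and 4 when adjusted over the list alone. RPP1A, a stalk protein (-0.87, adjusted p = 0.0194), RPL27B (-0.62, 0.0494) and RPL5 (-0.62, 0.0499) were those that fell; many of these genes have a near-identical paralog, so single values are uncertain. The median was -0.26 (camera adjusted p = 5.6e-12; adjusted p = 0.532 with an estimated correlation), and -0.13 after quantile normalization. Between the 2 wild-type cultures the median differed by -0.14. The 34 ribosome biogenesis genes, with 0 calls by either adjustment, had a median of -0.14 (camera adjusted p = 0.0173; adjusted p = 0.562 with an estimated correlation), a call lost without hst3hst4 replicate 2 and without wild-type replicate 2 (highest adjusted p = 0.302).

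Only 4 of 10 listed histone genes had a probe set of their own above the filter, and none passed over all genes while 3 fell adjusted over the list alone. Their log2 fold changes were -0.73 for HTB2 and -0.36 for HTB1, which encode histone H2B, -0.87 for the linker histone HHO1 and -0.04 for the H2A variant HTZ1. The list median of -0.55 passed (camera adjusted p = 0.014; adjusted p = 0.443 with an estimated correlation). Of 7 a-specific mating genes, STE6 fell and 6 did not pass, and 2 fell adjusted over the list alone; BAR1, the pheromone protease, had a log2 fold change of -0.69 (adjusted p = 0.11). The a-specific median was -0.45 (camera adjusted p = 0.00273; adjusted p = 0.443 with an estimated correlation). None of 11 haploid-specific genes passed over all genes and 3 fell adjusted over the list alone, among them FAR1, an inhibitor of G1 cyclin kinase, at -1.21 (adjusted p = 0.0848), and SST2, a regulator of pheromone signalling, at -0.82 (0.0638). Their median was -0.31 (camera adjusted p = 0.00478; adjusted p = 0.443 with an estimated correlation), and -0.46 without wild-type replicate 2.

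**Figure D2:**
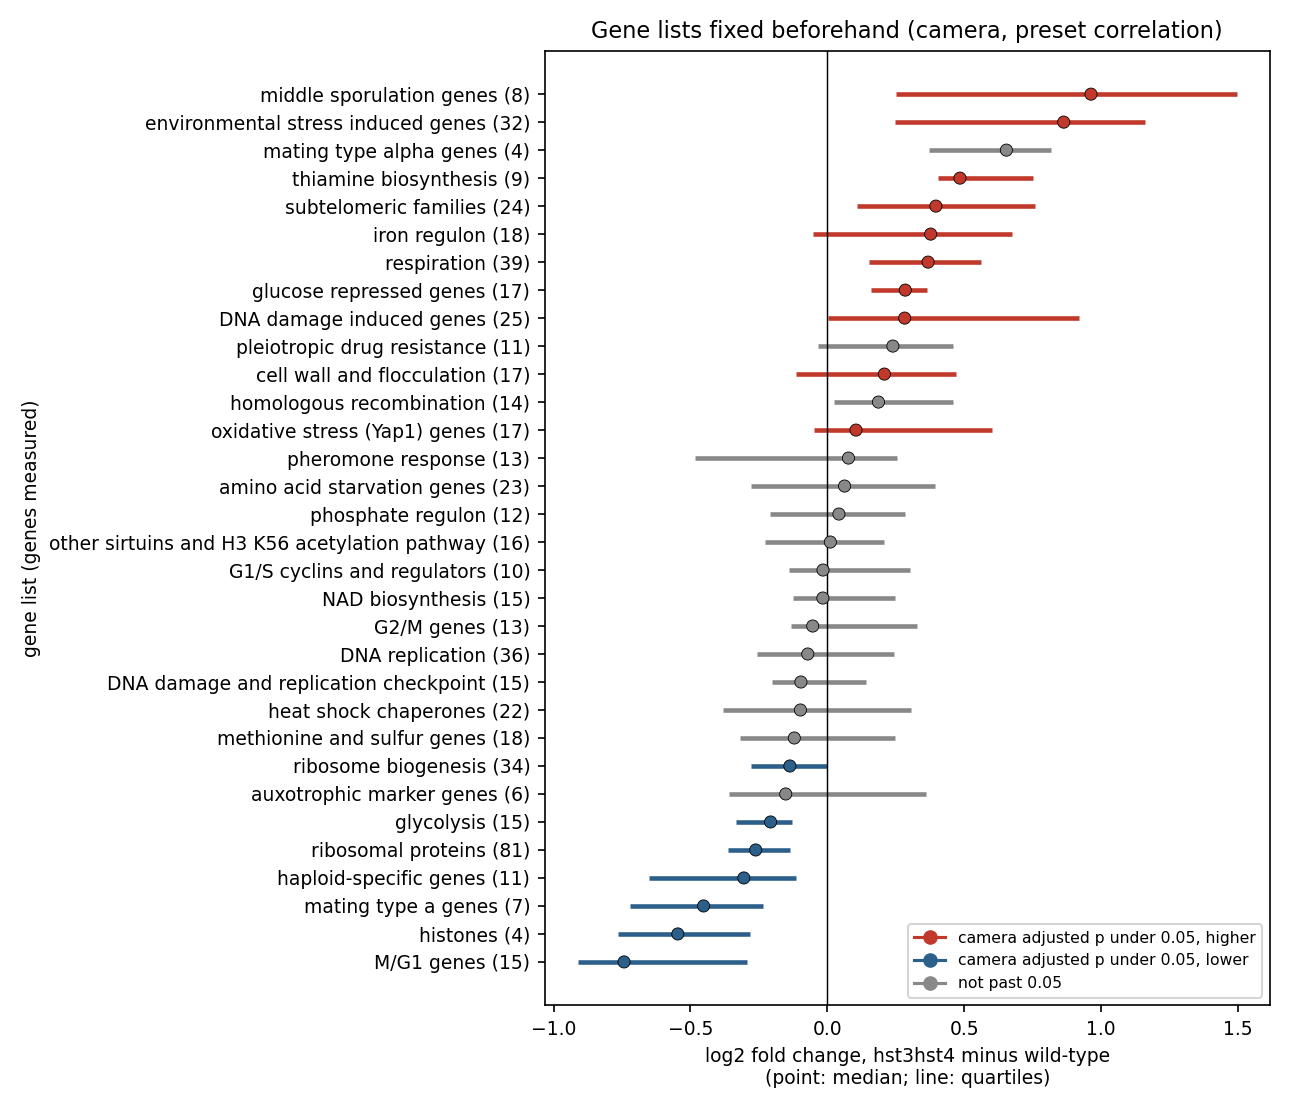
Median log2 fold change, hst3hst4 minus wild-type, of the members of each of 32 gene lists, with lines for the quartiles and the number of genes measured in parentheses. Red and blue mark lists that passed camera with the preset correlation, 10 higher and 7 lower, and grey those that did not; with an estimated correlation 0 passed.

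Over the 32 lists tested, 17 passed camera with the preset correlation of 0.01, 10 higher and 7 lower. With an estimated correlation 0 passed and 1 had an unadjusted p under 0.05, and fry, which asks whether the genes of a list move on balance in 1 direction, called 3: middle sporulation, subtelomeric families, and cell wall and flocculation. With an array left out, the median changed sign in 0 of the 17 called lists and in 10 of the 15 others: other sirtuins, checkpoint, DNA replication, G1/S, G2/M, pheromone response, markers, phosphate, NAD biosynthesis and heat shock chaperones.

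Chromosome-wide shifts were examined because a gain of a chromosome would raise all its genes together. In camera 0 of 16 chromosomes passed. The medians ran from -0.12 on chromosome 11 (adjusted p = 0.231) to 0.12 on chromosome 9 (adjusted p = 0.231), and these were the 2 chromosomes with an unadjusted p under 0.05 (0.0289 and 0.0145); with an estimated correlation 0 passed as well. Without hst3hst4 replicate 2, both of them passed (medians 0.10 for chromosome 9 and -0.17 for chromosome 11, adjusted p = 0.0358 for each). Among the arms, the right arm of chromosome 9 passed (40 genes, median 0.26, adjusted p = 0.0076). That call was lost without hst3hst4 replicate 1 (median 0.27) or wild-type replicate 1 (median 0.24). It was kept without hst3hst4 replicate 2 (median 0.21) or wild-type replicate 2 (median 0.35). In a test chosen after seeing the data, the call was also lost without the 8 outermost genes of each end (camera adjusted p = 0.354).

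**Figure D3:**
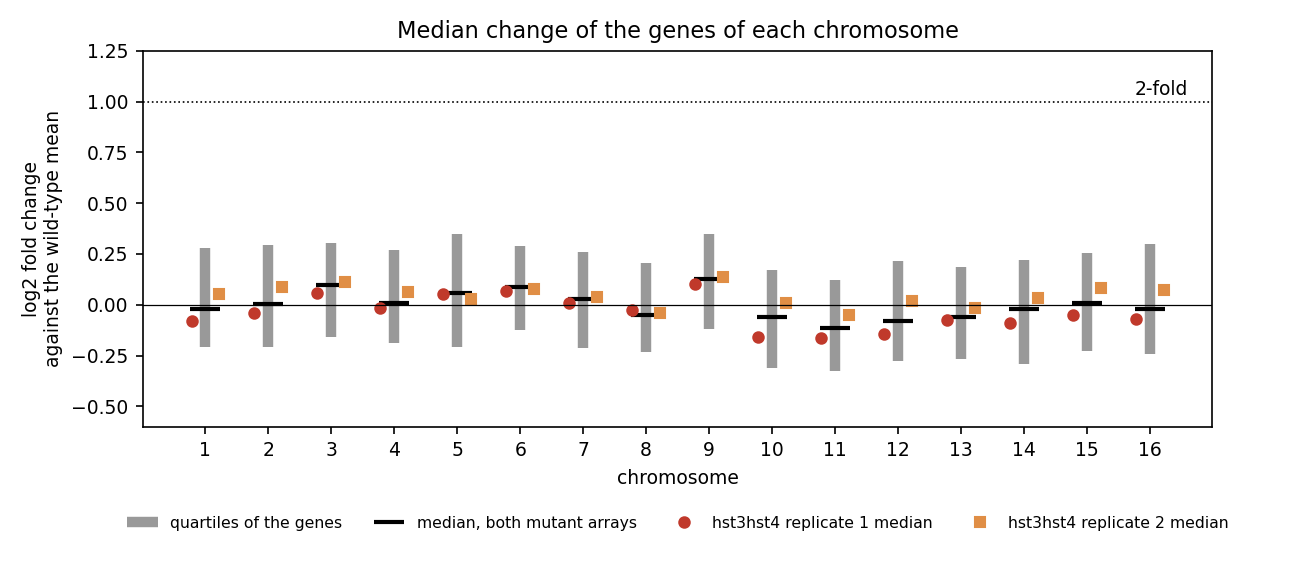
Log2 fold change of genes by chromosome, with grey bars for the quartiles, black ticks for the median, and circles and squares for the medians of hst3hst4 replicates 1 and 2 against the wild-type mean. The medians over both mutant arrays lie between -0.12 and 0.12 and those of single replicates between -0.17 and 0.14, all far below the dotted line at 2-fold.

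Genes at chromosome ends rose as a set. The 121 measured genes among the 8 outermost at each end had a median log2 fold change of 0.18, against -0.02 for all other genes (camera adjusted p = 0.00508, over the 6 end-gene tests run with the preset correlation; adjusted p = 0.152 with an estimated correlation, over 3 tests); 7 rose and 2, MMP1 and the dihydroorotate dehydrogenase URA1, fell. The median was 0.10 without wild-type replicate 1, 0.11 without hst3hst4 replicate 2 and 0.26 without hst3hst4 replicate 1. YAR068W (4.95-fold), COS8 (4.56-fold) and COS12 (3.14-fold) changed most among them, and COS genes form a subtelomeric family of related sequence. The 3 probe sets of COS8 gave 1.10, 2.19 and 2.37. The 39 measured genes among the 4 outermost had a median of 0.37 (camera adjusted p = 2.5e-06; adjusted p = 0.0814 with an estimated correlation) and the 296 among the 15 outermost a median of 0.07 (camera adjusted p = 0.0466; adjusted p = 0.239 with an estimated correlation). In an alternative chosen after seeing the data, without the subtelomeric families and probe sets of shared sequence, 90 genes of the 8 outermost had a median of 0.07. They did not pass camera (adjusted p = 0.158), while 20 genes of the 4 outermost, restricted in the same way, had a median of 0.40 and passed (adjusted p = 0.00295). The list of 24 subtelomeric family genes had a median of 0.40 (camera adjusted p = 3.2e-05; adjusted p = 0.443 with an estimated correlation); COS8 and COS12 rose and 22 did not pass, with 7 higher when adjusted over the list alone.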

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

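The test of swapped labels, that of the ribosomal protein list and the end genes without families were chosen after results had been seen. The arrays carry 13 control probe sets for yeast genes, which no test of expression used, though 6 of them entered the 3' to 5' ratios. Of the 13, 2 had both hst3hst4 arrays above both wild-type arrays and 7 had both below; chance alone gives each for 16.7% of probe sets, and several of the 13 belong to the same gene. Among the 7 lower probe sets the log2 ratios ran from -0.550, for the 3' probe set of the TATA-binding protein gene, to -0.085, for an ACT1 probe set. The WBP1 control had a log2 ratio of 0.153, with signals of 391 and 417 against 367 and 361. The URA3 control had a log2 ratio of 0.787, with 28.1 and 24.7 against 12.5 and 18.1. The probe set of URA3 among the tested ones had signals of 20.4 and 18.2 against 4.6 and 9.9 and did not pass (adjusted p = 0.158).

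HST4, which the labels say was deleted, was brighter on the arrays labelled hst3hst4. Raised transcription across the neighbourhood would bring along the 4 measured neighbours SLY1, RVB1, NUP42 and MSS116, and their median was -0.083, against 1.48, the smallest value set in advance for this explanation. Swapped strain labels are not settled. They would make both deleted genes brighter on the arrays labelled hst3hst4, as HST4 was. HST3 differed the other way (log2 difference -2.556). Its signals were 0.4 and 0.5 on those arrays, and 13.7 and 25.3 on the wild-type arrays, above the filter signal of about 8.97. Its mean over the 4 arrays lay below that filter, and where its probes lie is not known either. Also open are transcription read by probes outside the deleted part, from a marker or a remaining part of the gene, which could not be tested without probe positions, and a strain that differs from its label.

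The stress list was higher and the ribosomal protein list lower on the arrays labelled hst3hst4. A difference between cultures of the same strain, such as growth stage or handling, would show between the wild-type cultures as well. For the stress list it did: the absolute median difference between them was 0.822, while the smallest median of a mutant against a wild-type culture was -0.02, so this explanation may account for the list's shift. For the ribosomal protein list the wild-type cultures differed by 0.1415 and the smallest mutant against wild-type median was 0.145 in absolute size, too close to decide. The other lists were not put to this test. A response to the deletions stays open and was not tested apart from growth.

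Chromosome-end genes were higher on the arrays labelled hst3hst4. A drift of dim genes does not account for it, since none of 10000 random lists matched on expression reached the observed median, a share of 0.01% at the smallest that they can give. Sequence shared among subtelomeric families could carry part of it: without families and shared-sequence probe sets the 8 outermost at each end had a median of 0.0713 and the 4 outermost 0.40, over 90 and 20 genes. In camera the adjusted p = 0.158 for the former and the adjusted p = 0.00295 for the latter. The 2 values differ in what they leave, and the explanation is not settled. An effect of the deletions on genes near telomeres is a hypothesis that stays open.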

How the results depend on the processing

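All 196 called probe sets kept their direction in every setting in which they were tested. For the called genes, whose sign was the same in all 4 array pairs, only another normalization could have changed the direction. This therefore adds little support to the calls. The number called was 36 with no filter, 38 without a trend, 1189 on the added hybridisation-control scaling, which shifts every probe set alike, and 4 to 865 with an array left out, where the lone array of a strain is assumed to vary like the other strain; the causes were otherwise not tested. With the replicate number as a block it was 343. Same-numbered arrays did not deviate together (correlation -0.041), and the labels do not say whether the numbers mark a shared day. The 2-fold count of 122 was 76 with a pseudocount at the 25th percentile, which shrinks the folds of dim genes, 192 with no filter, 386 at 1.5-fold and 223 to 381 with an array left out, where 2 pairs remain. The HST4 log2 fold change was 3.75 with a pseudocount of 1 and 1.77 with one at the 25th percentile (HST3 -3.76 and -1.26), and 2.60 to 3.32 with an array left out, its call lost without either mutant array. Of the 17 list calls, 10 held in all 11 settings of normalization, pseudocount, filter, block and arrays left out, but 0 held with an estimated correlation and 3 lists passed fry. The phosphate regulon reversed, to -0.443 without wild-type replicate 1, and ran up to 0.574. Chromosome arms gave 1 call, and 0 to 2 chromosomes passed with an array left out. The chromosome-end median was 0.182 with its call lost under an estimated correlation, and 0.0713 with families left out. For named genes, 518 of 648 values with an array left out and 1339 of 1424 under other settings kept their side of the threshold. Of 44 values with the other sign, in 24 genes, 0 belonged to a gene called in either fit. For genes called in the main fit this too was largely fixed in advance by their sign in the array pairs. Signals near the background limit dim genes such as HST3.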

Other observations

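The test of an extra chromosome arm, and the adjustment over all arms of the test without the outermost genes, were chosen after results had been seen. Of 8 measured middle sporulation genes, SGA1, a glucoamylase of sporulating cells (3.03-fold), and SPS19, a peroxisomal dienoyl-CoA reductase (log2 fold change 1.38), rose and 6 did not pass; adjusted over the list alone, 4 rose. Only 8 of 19 listed genes had a probe set of their own above the filter. The list median was 0.96 (camera adjusted p = 0.00273, and adjusted p = 0.443 with an estimated correlation). It was 0.53 with no filter and 0.40 with a pseudocount of 1. FIT2, a cell wall mannoprotein that retains siderophores, rose 4.33-fold, the only call among 18 iron regulon genes (4 higher adjusted over the list alone). The wild-type cultures differed on these genes by a median of -0.33, and the median of the array pairs ran from 0.20 to 0.39. The iron list had a median of 0.38 (camera adjusted p = 0.0141; adjusted p = 0.443 with an estimated correlation), and lost its call without hst3hst4 replicate 1 or wild-type replicate 1 (highest adjusted p = 0.134; median 0.25 in the latter). THI7, the thiamine transporter, rose 3.15-fold, the only call among 9 thiamine genes by either adjustment, all of which were above 0. On these genes the wild-type cultures differed by a median of -0.53, and the median of the 4 array pairs ran from 0.16 to 0.90. The thiamine list had a median of 0.48 (camera adjusted p = 0.00322; adjusted p = 0.562 with an estimated correlation), 0.27 without wild-type replicate 1, where the call was lost (adjusted p = 0.197), and 0.90 without wild-type replicate 2. Of 17 oxidative stress genes, the sulfiredoxin SRX1 (2.98-fold), the NADPH oxidoreductase OYE3 (2.62-fold) and the transporter FLR1 (log2 fold change 1.27) rose and 14 did not pass; adjusted over the list alone, 5 rose. That list had a median of 0.10 and a mean of 0.36 (camera adjusted p = 0.0173; adjusted p = 0.443 with an estimated correlation), 0.20 after quantile normalization, 0.06 without hst3hst4 replicate 2, and no call without wild-type replicate 1 (adjusted p = 0.0533).

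Several lists did not pass camera although single members changed. BNA2 was the only call among 15 NAD biosynthesis genes (median -0.02, camera adjusted p = 0.853; 2 higher and 1 lower adjusted over the list alone), with BNA4 at 1.04 (adjusted p = 0.0695). Of 18 methionine and sulfur genes, MMP1, MET6 and the S-adenosylmethionine synthetase SAM2 fell (median -0.12, camera adjusted p = 0.249; 3 lower adjusted over the list alone). ARG1, argininosuccinate synthetase, rose 4.66-fold as the only call among 23 amino acid starvation genes (median 0.06, camera adjusted p = 0.55; 2 higher and 1 lower adjusted over the list alone). RTA1 (2.85-fold) and the transporter PDR10 (2.18-fold) rose among 11 drug resistance genes (median 0.24, camera adjusted p = 0.0802; 2 higher adjusted over the list alone), a list that passed without wild-type replicate 2 (median 0.39, adjusted p = 0.00466) or without hst3hst4 replicate 1 (median 0.29, adjusted p = 0.0208) but had a median of 0.09 without wild-type replicate 1 (adjusted p = 0.732) and 0.15 without hst3hst4 replicate 2 (adjusted p = 0.265). PHM8 rose 2.18-fold among 12 phosphate genes (median 0.04, camera adjusted p = 0.55; 1 higher adjusted over the list alone), a list on which the wild-type cultures differed by a median of -1.08. The median of this list was -0.44 without wild-type replicate 1 (adjusted p = 0.0226) and 0.57 without wild-type replicate 2 (adjusted p = 2.4e-05). None of 13 pheromone response genes passed (median 0.08, mean -0.08, camera adjusted p = 0.55; 2 lower adjusted over the list alone), and the median ran from -0.13 without hst3hst4 replicate 2 to 0.19 without hst3hst4 replicate 1. None of 4 alpha-specific genes passed by either adjustment (median 0.65, camera adjusted p = 0.129), and that list passed without wild-type replicate 2 (median 1.05, adjusted p = 0.0117) but not without wild-type replicate 1 (median 0.26, adjusted p = 0.521). Of 6 measured marker genes LEU2 fell and 5 did not pass (median -0.15, camera adjusted p = 0.45; 1 higher and 1 lower adjusted over the list alone), and the median ran from -0.28 without wild-type replicate 1 to 0.01 without wild-type replicate 2. HIS3 stayed between 0.2 and 3 on all 4 arrays in both of its probe sets.

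The largest decrease of any called probe set belonged to 2435_at, for which no gene is listed: its signals were 1.2 and 9.2 on the hst3hst4 arrays and 245 and 182 on the wild-type arrays (log2 fold change -4.84, adjusted p = 0.00243). Its hst3hst4 signals lay near or below the filter signal of about 8.97, so the size of this decrease depends on the pseudocount. The probe set was singled out after its values were seen.

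LEU2 signals were 1260 and 1327 on the hst3hst4 arrays and 2873 and 2875 on the wild-type arrays. A second probe set of LEU2 had a log2 fold change of -1.16 (limma adjusted p = 0.0141). LEU2 is also on the list of marker genes. A candidate explanation is lower activity of its regulator Leu3, and no other explanation was tested. The 6 other Leu3-regulated genes measured had a median of -0.2512, above the -0.58 that a shift of the kind seen in LEU2 would need, but went both ways, from ILV2 at -0.59 to GDH1 at 0.52, so this was not decided.

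A hypothesis that neighbouring genes rose together found no backing. Only 2 adjacent pairs of measured genes both rose, GTT1 with YPS6 and BNA2 with YJR079W, and shuffling the calls along the chromosomes gave a median of 2 (permutation p = 0.728, one-sided, 10000 shuffles).

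The right arm of chromosome 9 was higher by a median of 0.26 over 40 genes, 30 of them above 0 and 3 called higher, DAL1 (allantoinase), GTT1 (a glutathione transferase) and YPS6 (an aspartic protease). Its call was lost without hst3hst4 replicate 1 (median 0.27) or wild-type replicate 1 (median 0.24), and kept without either replicate 2. Whether the outermost genes alone could account for it is not settled: the 32 genes outside the 8 outermost had a median of 0.1743, with an unadjusted p = 0.0258 in camera with the preset correlation. The prediction fixed beforehand used that p, but the arm was picked as the highest of 32, and over the arms without their outermost genes the adjusted p = 0.354. A full extra copy in every cell would need at least 0.58, and the arm's median was 0.2634 with a standard error of 0.0628. An extra copy in part of the cells may still be at work and was not tested.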
